A study of Mus musculus with 14 samples.

How the data were processed

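Total RNA of 14 mouse samples in 6 groups was hybridised to Illumina MouseRef-8 v2.0 expression BeadChips. Per the file headers, the deposited non-normalized table gives a bead signal intensity and a detection p-value for each of 25697 probes and 14 arrays; whether a background was subtracted is not stated, and no value was 0 or negative. The deposited value table of the authors holds intensity on a linear scale; checked against the non-normalized intensity, each column had the same ranks (Spearman 1) and the same minimum and maximum (94.67 and 17113), as quantile normalization without background correction gives. The labels name lumi as the processing tool, without a version. Samples were matched to columns by name, and 0 columns belonged to no sample. Signals of 4 fibroblast arrays (Y-SC 16, Y-SC 17, A-SC 1.3 and A-SC 1.4) were written with 1 decimal and a higher maximum than the other 10. This export format was examined as a possible technical batch in alternative fits only, and the reported fit does not adjust for it. Array medians were 110.656 to 147.6 and the percent of probes detected 47.6 to 52.3.

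The non-normalized intensity was processed in R 4.3.3 with limma 3.58.1. The function neqc corrected background with negative controls inferred from the detection p-values, added an offset of 16, quantile normalized and took log2. Of the probes, 14742 with a detection p under 0.05 on every array of at least 1 group were tested, for 10004 genes. Gene symbols came from the probe annotation, updated through the gene ID for 23962 of the 23978 probes with a symbol; 1719 had none. The gene table of assembly GRCm38.p6 gave names and grouped genes by chromosome, and no coordinates are given. Linear models had 1 mean per group over all 14 arrays, with a pooled spread of 8 residual degrees of freedom moderated by empirical Bayes (prior degrees of freedom 3.633). The 10 comparisons were contrasts of this fit, and a probe passed at a Benjamini-Hochberg adjusted p under 0.05 over the tested probes. Clone codes do not pair arrays between groups.

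Gene lists, 29 in number, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of each comparison; camera with an estimated correlation and fry were run beside it. A gene was represented by its tested probe with the highest mean. Named genes followed a rule: the 6 highest and 6 lowest (3 and 3 in the contrasts with ESC, A-iPSC-ZSCAN10 minus Y-iPSC and the difference of reprogramming changes) that passed with groups that did not overlap, up to 4 passing members of each list, and in every comparison Zscan10, Pou5f1, Sox2, Klf4, Myc, Gss, Gpx2, Slc2a3, Exosc1, Exosc2 and Exosc5. Not every gene chosen by this rule is printed below, and Myc is given no value of its own. Members that moved against their list were named after the values were seen. With 2 arrays against 2, groups do not overlap by chance with a probability of 0.333. Where 1 group had no detected array, the fold was computed against the lowest normalized value of a detected probe on those arrays. The test, filter, lists, naming rule and the alternatives of background, normalization, filter, prior, array weights, probe averaging, arrays in the fit and left-out arrays were chosen before the data were examined. Export format as a block, fits without or within the second format, fits without probes of the X and Y chromosomes, and the split of the A-iPSC arrays between both comparisons were chosen after seeing the data.

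The steps were tested on simulated data with 14742 probes, 3 runs and 40 changed probes per size and run. In A-iPSC minus Y-iPSC, 5% of probes changed by 1 log2 unit were recovered, 70% at 2 and 95% at 3; in A-SC minus Y-SC these were 20.83%, 82.5% and 99.17%, and in the difference of reprogramming changes 1.667%, 46.67% and 79.17%. The false share of calls was 3.58% to 6.13% over the comparisons. The simulated noise was independent between probes and had the same spread in every group. Real replicate arrays correlated at 0.9321 in Y-iPSC and 0.9858 in ESC, so these rates need not hold for the measured data.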

Results

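Gene expression was measured on 14 bead arrays of mouse cells, each with 25697 probes. There were 3 arrays of fibroblasts from embryonic skin of young donors (Y-SC), 3 of fibroblasts from tail tip skin of aged donors (A-SC), and 2 each of induced pluripotent stem cells (iPSC) from young fibroblasts (Y-iPSC), iPSC from aged fibroblasts (A-iPSC), iPSC from aged fibroblasts with doxycycline-inducible ZSCAN10 (A-iPSC-ZSCAN10) and embryonic stem cells (ESC). The iPSC had received retroviral Oct4, Sox2, Klf4 and Myc. Median probe intensity was 110.656 to 147.6 per array, and 47.6% to 52.3% of probes were detected. The number of arrays limits the precision. Young and aged donors also differed in developmental stage and body site, and age is confounded with these. The labels do not say whether arrays of a group are separate cultures or animals, so p-values measure only the spread between these samples. Fold changes below are log2 values ± SE with adjusted p from limma. Where 1 group had no array with the gene detected, the fold is a lower bound against the detection limit.

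The first question was how iPSC from aged donors differed from iPSC of young donors. Gpx2, a glutathione peroxidase, rose in A-iPSC by 5.33 ± 0.26 (adjusted p = 8.38e-07, n = 2 arrays per group). Not every Y-iPSC array detected Gpx2, so this size depends in part on the offset added to the signal. Htr2b, a serotonin receptor, was at least 76.9-fold higher. Slc2a3, the glucose transporter GLUT3, fell with a log2 fold change of -5.90 ± 0.57 (adjusted p = 0.000112). Zscan10, a zinc finger factor of pluripotent cells, was lower in A-iPSC at -2.17 ± 0.38 (adjusted p = 0.0047). A-iPSC 19 did not detect it, so its size also depends in part on the offset. Gss, the glutathione synthetase, was higher at 1.47 ± 0.35 (adjusted p = 0.0223). Other genes at the top were Gsta3, a glutathione transferase (5.41 ± 0.91), Guca1a, a guanylate cyclase activator (5.27 ± 0.46), Cd74, the invariant chain of class II antigen presentation (5.16 ± 0.50), and the homeobox gene Hoxd10 (5.10 ± 1.32). Genes of keratinised epithelium lay at the bottom: Krt42 was at least 83.0-fold, Krtdap at least 69.8-fold and Krt17 at least 48.9-fold lower, and Lgals7, galectin 7, was at -6.26 ± 0.39. Of 14 keratinocyte markers, 4 fell and 0 rose (4 adjusted over the list alone; camera adjusted p = 0.0908). Erdr1 was at least 56.5-fold lower. Of the 4 reprogramming factors Pou5f1, Sox2, Klf4 and Myc, 0 passed (0 adjusted over the list alone, camera adjusted p = 0.505).

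In the naive pluripotency list, 7 of 25 measured genes fell in A-iPSC, 0 rose and 18 did not pass (9 fell adjusted over the list alone). Gdf3, a TGF-beta family ligand of pluripotent cells, was at least 40.7-fold lower, Fbxo15 fell with -2.87 ± 0.27 and L1td1 with -2.13 ± 0.28. The list shifted down by camera (adjusted p = 0.000157; adjusted p = 0.627 with an estimated correlation). Of 37 glutathione genes, 7 rose, 1 fell and 29 did not pass (10 and 1 adjusted over the list alone), with Gstt1 at 2.17 ± 0.48 and Gstp2 lower at -3.13 ± 0.69. The camera adjusted p was 0.0464 (adjusted p = 0.786 with an estimated correlation). Among 25 other antioxidant enzymes, 3 rose and 0 fell (5 and 0 adjusted over the list alone): Sesn1 at 1.65 ± 0.34, Glrx at 1.61 ± 0.37 and Nfe2l2, the oxidative stress regulator NRF2, at 1.54 ± 0.44. That list had a camera adjusted p of 0.0464 (adjusted p = 0.457 with an estimated correlation). Cell cycle genes shifted down as a list (adjusted p = 0.00379; adjusted p = 0.786 with an estimated correlation and 0.376 with fry), though of 38 only Mcm3, a replication licensing helicase subunit, fell (-2.13 ± 0.59; 0 adjusted over the list alone).

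DNA repair genes went both ways in A-iPSC, with 3 of 61 higher and 3 lower (also 3 and 3 adjusted over the list alone; camera adjusted p = 0.112). Apex1, the base excision repair endonuclease, fell with -1.90 ± 0.28, while Rad52 rose by 1.66 ± 0.24 and Polb, DNA polymerase beta, by 1.33 ± 0.31. For the RNA exosome and its cofactors, 2 of 18 rose and 1 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.248). Ttc37, a subunit of the Ski complex that feeds RNA to the exosome, rose by 2.07 ± 0.22. The core subunits Exosc1, Exosc2 and Exosc5 had log2 fold changes of -0.48, -1.42 and -0.80 and did not pass (adjusted p = 0.337, 0.126 and 0.0551). Extracellular matrix genes were split, with 4 of 38 higher, such as Ccdc80 at 3.61 ± 0.45, and 3 lower, such as Sparc at -2.43 ± 0.42 (4 and 4 adjusted over the list alone; camera adjusted p = 0.506). Basement membrane collagens Col4a1 and Col4a2 fell with -3.35 ± 0.42 and -3.91 ± 0.42, and the neural factor Zic1 was at least 23.8-fold lower.

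In all, 1495 of 14742 probes passed, 891 higher and 604 lower in A-iPSC, for 1050 genes. The count was 418 without A-iPSC 19, 839 without Y-iPSC 4, 886 without A-iPSC 16, and 182 with only these 4 arrays in the fit. The calls of Zscan10 and Gss were lost without A-iPSC 19, and that of Gss also without A-iPSC 16 or Y-iPSC 4. With only these 4 arrays the calls of Zscan10, Gss, Slc2a3 and Gsta3 were lost, and Hoxd10 did not pass in any fit that left out 1 of them. Of 70 named genes past the threshold, 30 passed in every such fit, Gpx2, Gdf3 and Htr2b among them.

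**Figure D1:**
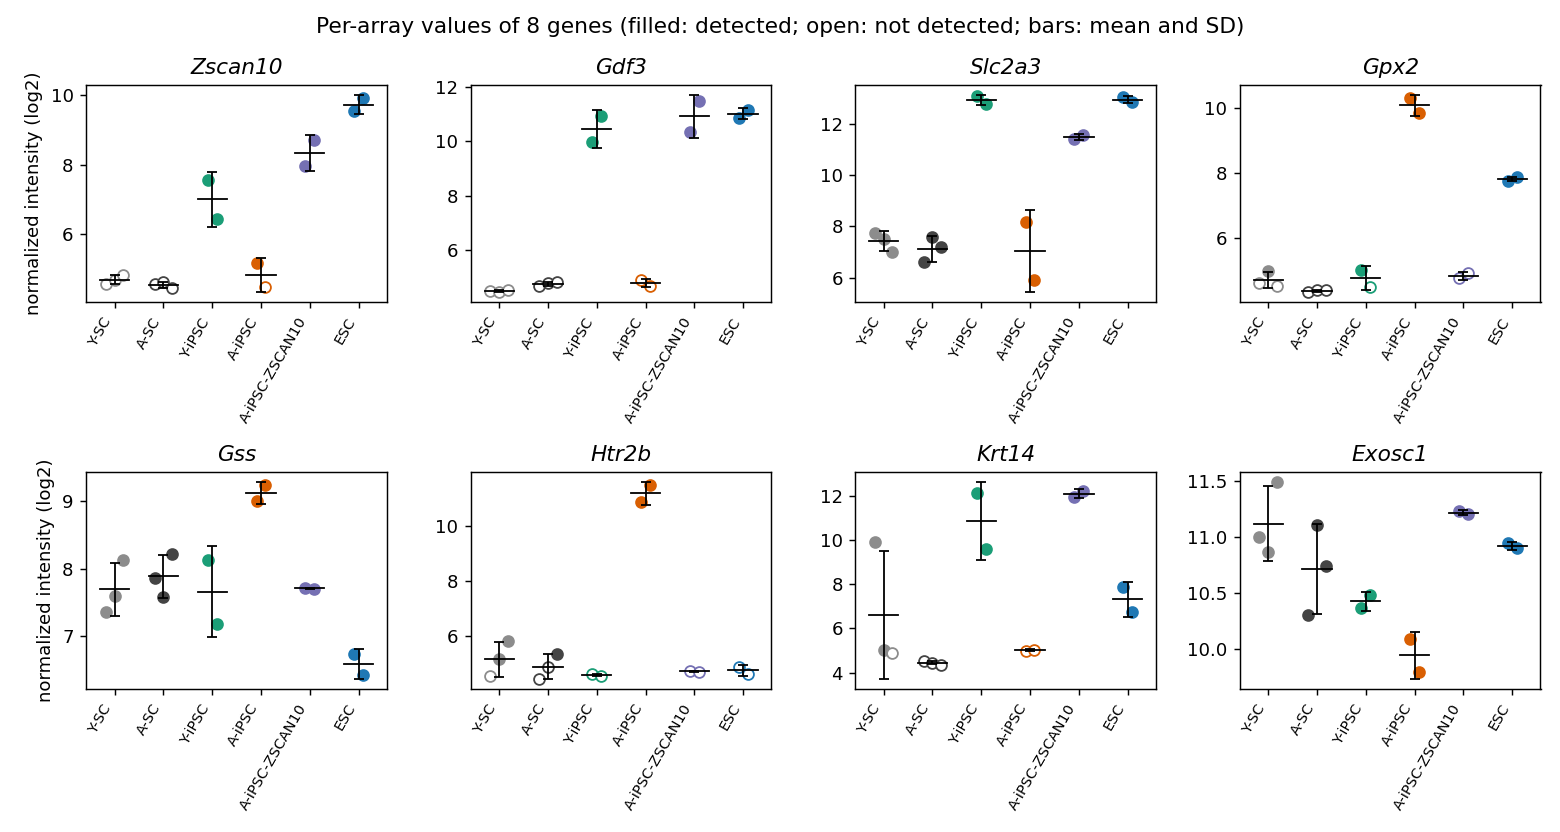
Normalized log2 intensity of 8 genes on each of the 14 arrays by group; filled points are detected, open points are not, and bars show the mean and SD. Gpx2 and Htr2b lie highest in A-iPSC, and Gdf3 lies near the detection limit in A-iPSC and in the fibroblasts.

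A second comparison asked how iPSC of aged donors made with inducible ZSCAN10 differed from those made without it. The labels give doxycycline for induction of ZSCAN10 alone, so doxycycline exposure is confounded with ZSCAN10, and the lines were made separately. Zscan10 itself rose by 3.51 ± 0.38 (adjusted p = 0.000225, n = 2 arrays per group). That size depends in part on the offset, as A-iPSC 19 did not detect Zscan10, and whether its probe reads the introduced copy is not stated. Gdf3 was at least 56.1-fold higher in A-iPSC-ZSCAN10 and Slc2a3 rose by 4.46 ± 0.57 (adjusted p = 0.000645). Gpx2 was at least 33.8-fold lower, Htr2b at least 73.4-fold lower and Gss fell with -1.41 ± 0.35 (adjusted p = 0.0194). Keratin 14, Krt14, of basal epidermis, was at least 128-fold and Krt42 at least 34.3-fold higher, with Lgals7 at 6.56 ± 0.39. The cytochrome P450 gene Cyp2b23 was at least 27.8-fold higher, and the acute phase gene Saa3 rose by 4.94. Guca1a (-6.12 ± 0.46), Mansc1 (-5.92 ± 0.82), the spectrin gene Sptb (-5.04 ± 0.43) and Shisa2 (-4.86 ± 0.44) were the other lowest genes. Of the 4 reprogramming factors, 0 passed (0 adjusted over the list alone, camera adjusted p = 0.474).

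Fibroblast and extracellular matrix genes rose in A-iPSC-ZSCAN10, with 17 of 38 higher, 2 lower and 19 not past (18 and 3 adjusted over the list alone). Tgfbi, a matrix protein induced by TGF-beta, rose by 4.81 ± 1.27, the mesenchymal factor Twist2 by 4.30 ± 0.74, the collagen gene Col6a1 by 4.27 ± 1.13 and S100a4 by 3.76 ± 0.55, while Twist1 and Ccn1 fell (log2 fold change -1.58 and -2.42). The list's camera adjusted p was 5.88e-06 (adjusted p = 0.563 with an estimated correlation). Group mean correlation across genes with Y-SC, where genes are not independent replicates, was 0.8721 for A-iPSC-ZSCAN10, 0.8264 for Y-iPSC and 0.8123 for A-iPSC. Of 25 naive pluripotency genes, 8 rose and 1 fell (10 and 1 adjusted over the list alone), among them Fbxo15 at 2.58 ± 0.27 and Dppa5a at 2.99 ± 0.86, while Klf2 was the member that fell, at -1.86 (camera adjusted p = 0.000245; adjusted p = 0.563 with an estimated correlation). The naive list holds Zscan10, the gene introduced in this group, which was among those that rose. Glucose uptake and glycolysis genes fell, 8 of 26 lower and 1 higher (12 and 1 adjusted over the list alone). The member that rose was Slc2a3, and Aldoc, an aldolase, fell with -4.47 ± 0.60, the enolase Eno2 with -3.41 ± 0.61 and the lactate exporter Slc16a3 with -2.63 ± 0.67 (camera adjusted p = 0.000166; adjusted p = 0.563 with an estimated correlation).

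Cell cycle genes shifted up, with 4 of 38 past the threshold (0 adjusted over the list alone): Mcm2, Mcm3, Mcm4 and cyclin E1, Ccne1, at 1.82 ± 0.56, 2.08 ± 0.59, 1.66 ± 0.48 and 1.94 ± 0.54 (camera adjusted p = 0.00059; adjusted p = 0.627 with an estimated correlation and 0.21 with fry). Interferon response genes fell as a list, 4 of 30 lower (3 adjusted over the list alone), such as Oas2 at -2.54 ± 0.55 and Ifi35 at -1.70 ± 0.35. The list's camera adjusted p was 0.0268 (adjusted p = 0.627 with an estimated correlation and 0.21 with fry). Of 34 p53 genes, 4 fell and 1 rose (5 and 1 adjusted over the list alone), with Rrm2b, a ribonucleotide reductase subunit, at -1.13 ± 0.30, and Sfn, also a keratinocyte marker, higher at 3.55. The p53 list's camera adjusted p was 0.0374 (adjusted p = 0.627 with an estimated correlation and 0.134 with fry). Glutathione genes had 7 of 37 lower and 2 higher (9 and 3 adjusted over the list alone; camera adjusted p = 0.174), with Mgst1 at -3.72 ± 1.01 and Gpx8 higher at 3.14 ± 0.47. In the exosome list, 4 of 18 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.0703). Exosc1 rose by 1.28 ± 0.29, Exosc4 by 1.12 ± 0.30 and Exosc5 by 0.96 ± 0.24, Ttc37 fell with -1.94 ± 0.22, and Exosc2 was at 1.76 ± 0.55 and did not pass (adjusted p = 0.0503). The DNA repair list had 6 of 61 members lower and 1 higher (1 and 1 adjusted over the list alone) beside a median of 0.43 and a mean of 0.38 (camera adjusted p = 0.186). Xpc, a damage sensor of nucleotide excision repair, fell with -1.78 ± 0.33, and Apex1 rose by 1.96 ± 0.28.

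Of the 14742 probes, 1080 were higher and 1234 lower in A-iPSC-ZSCAN10, 2314 in 1616 genes. The direction of the majority depends on the scaling, with 1515 higher and 963 lower under median scaling and 909 and 1333 under cyclic loess. The count was 714 without A-iPSC 19, 755 without A-iPSC-ZSCAN10 7, 1148 without A-iPSC-ZSCAN10 3 and 1439 without A-iPSC 16, 3910 with only these 4 arrays and 4874 with array weights. Gss and Exosc5 did not pass in any of the 4 fits that left out 1 of these arrays, and Exosc1, Tgfbi and Dppa5a each lost their call in 3 of the 4. Of 82 named genes past the threshold, 33 passed in all 4.

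Many probes moved in opposite directions in both comparisons: 653 higher in A-iPSC than in Y-iPSC were lower in A-iPSC-ZSCAN10 than in A-iPSC, and 348 the other way. Gpx2, Htr2b, Gss and Ttc37 were of the first kind, and Zscan10, Gdf3, Slc2a3, Fbxo15 and Apex1 of the second. Zscan10 was the gene introduced in A-iPSC-ZSCAN10, so its rise there may come from the introduced copy. Same-direction calls numbered 4. Both comparisons use the same A-iPSC arrays, so noise in these arrays also gives opposite signs: over 50 simulations of unchanged groups, the correlation of fold changes across genes, which are not independent replicates, was -0.501 against -0.752 observed. With the A-iPSC arrays split, so that no array served both comparisons, opposite calls numbered 274 (A-iPSC 16 against Y-iPSC) and 375 (A-iPSC 19 against Y-iPSC), beside 21.16 and 23.25 for independent lists and 3 and 4 of the same sign. The correlation across genes was then -0.643 and -0.669. Gpx2, Htr2b, Ttc37, Gdf3, Slc2a3, Fbxo15 and Apex1 were among the opposite calls in both splits, Zscan10 in 1 and Gss in 0. Each split rests on a lone A-iPSC array per comparison, assumed to vary like the other groups. The count was 295 without A-iPSC 19, 461 without A-iPSC-ZSCAN10 7, 626 without Y-iPSC 4, 637 without A-iPSC 16 and 660 without A-iPSC-ZSCAN10 3.

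**Figure D2:**
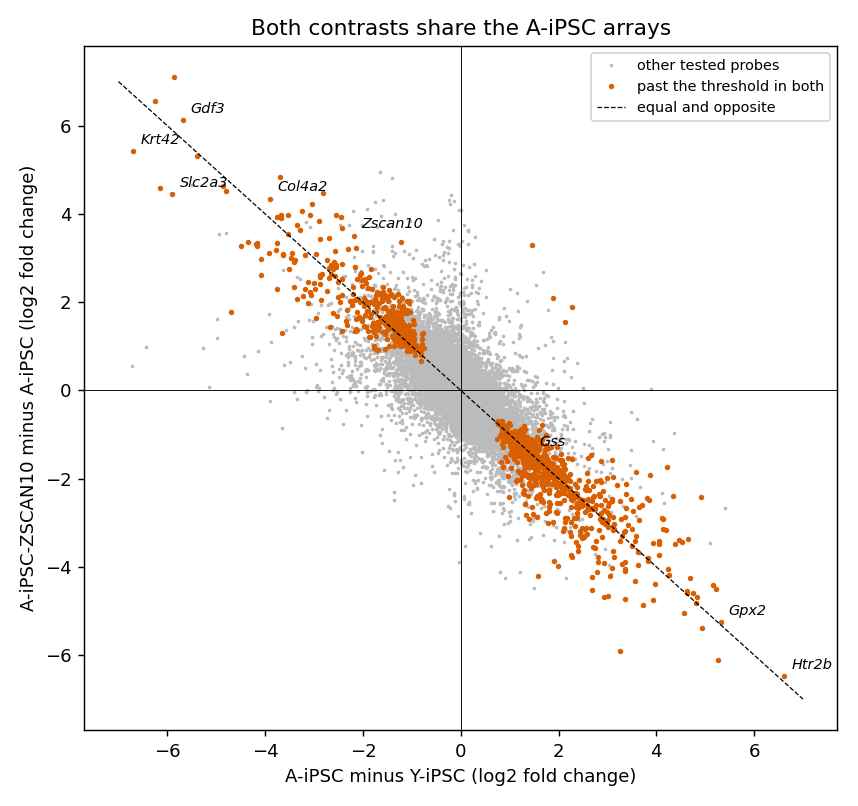
Log2 fold change of A-iPSC minus Y-iPSC against A-iPSC-ZSCAN10 minus A-iPSC for the 14742 tested probes; orange points passed in both and the dashed line marks equal and opposite changes. Most orange points lie along the dashed line, and both axes use the same A-iPSC arrays.

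Set directly against Y-iPSC, A-iPSC-ZSCAN10 differed at 198 probes, 93 higher and 105 lower (129 and 113 under median scaling), in 145 genes. Bmper, a BMP regulator, rose by 4.76 ± 0.39, the matrix proteoglycan Prelp by 4.36 ± 0.81 and the prostaglandin transporter Slco2a1 by 4.17 ± 0.45 (n = 2 arrays per group). Zic1 was at least 25.4-fold lower, Krtdap fell with -6.18 ± 0.90 and Erdr1 with -5.44 ± 0.96. Of 38 matrix genes, 6 rose and 1 fell (12 and 1 adjusted over the list alone), with Twist2 at 4.17 ± 0.74 and biglycan, Bgn, at 2.57 ± 0.23 (camera adjusted p = 1.67e-08; adjusted p = 0.445 with an estimated correlation). Among 30 interferon genes, Ly6e fell with -2.50 ± 0.32 (1 lower; 10 lower adjusted over the list alone), and the list shifted down (camera adjusted p = 1.07e-09; adjusted p = 0.445 with an estimated correlation). The p53 list (0 of 34 past) and the glycolysis list (1 of 26 lower, Aldoc at -2.97 ± 0.60; 2 adjusted over the list alone) shifted down with camera adjusted p of 0.00052 and 0.000579, and with adjusted p = 0.597 and adjusted p = 0.445 with an estimated correlation. With fry, which does not compare a list with other genes, the matrix, interferon, p53 and glycolysis lists did not pass (adjusted p = 0.0688, 0.0814, 0.178 and 0.0694). Of 25 naive pluripotency genes 0 passed (0 adjusted over the list alone; camera adjusted p = 0.925), with a median of -0.02 and a mean of 0.06. Of the 4 reprogramming factors, 0 passed (2 lower adjusted over the list alone, camera adjusted p = 0.052). Zscan10, Slc2a3 and Gss did not pass, at 1.33 ± 0.38, -1.44 ± 0.57 and 0.05 ± 0.35. Gpx2 did not pass either and was detected on 1 of 2 Y-iPSC arrays and 0 of 2 A-iPSC-ZSCAN10 arrays. A limma fit of these 4 arrays alone gave 0 probes, with 1816 at an unadjusted p under 0.05. The count was 66 without A-iPSC-ZSCAN10 3 and 769 without Y-iPSC 12.

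Against ESC, the naive pluripotency network was the group that moved furthest in each iPSC group. Of its 25 measured genes, 18 were lower in Y-iPSC, 24 in A-iPSC and 17 in A-iPSC-ZSCAN10, and 0 were higher (19, 25 and 21 lower adjusted over the list alone). Dnmt3l, a cofactor of DNA methylation, was at least 256-fold, 229-fold and 244-fold lower in Y-iPSC, A-iPSC and A-iPSC-ZSCAN10. Esrrb, a nuclear receptor of naive cells, fell with -7.86 ± 0.25 in Y-iPSC and -7.91 ± 0.25 in A-iPSC-ZSCAN10, and was not detected in A-iPSC. It was also not detected on Y-iPSC 4 and A-iPSC-ZSCAN10 3, so these sizes depend on the offset. Its share of the ESC signal was 0.0835% to 0.291% over the iPSC arrays. Nanog was at least 127-fold lower in A-iPSC. A-iPSC 19 did not detect Zscan10, so the size of Zscan10 in A-iPSC depends in part on the offset. Zscan10 was at -2.72 ± 0.38, -4.90 ± 0.38 and -1.39 ± 0.38, the last no longer past under median scaling, without a filter, or without A-iPSC-ZSCAN10 3, ESC D or ESC H. The camera calls of this list held with an estimated correlation (adjusted p = 0.0335, 0.0294 and 0.0302), as did that of trophectoderm genes in A-iPSC-ZSCAN10 (adjusted p = 0.0314); these are the 4 of 73 calls over the 10 comparisons that did. Trophectoderm genes had 11 of 16 lower and 2 higher there, with Krt18 at -6.13 ± 1.16 (11 and 2 adjusted over the list alone); 7 were lower and 2 higher in Y-iPSC, and 11 and 3 in A-iPSC (9 and 2, and 12 and 3, adjusted over the list alone).

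Claudin gene Cldn11 was at least 430.5-fold, 171-fold and 150.0-fold higher than in ESC in Y-iPSC, A-iPSC and A-iPSC-ZSCAN10, and the amino acid transporter Slc38a5 rose by 8.01 ± 0.24, 7.53 ± 0.24 and 8.09 ± 0.24. Mesoderm genes fell, 8, 12 and 11 of 19, with 1 member, Tbx6, higher in A-iPSC at 1.62 (11, 12 and 11 lower adjusted over the list alone), with Cdx1 at -3.29 ± 0.36, -3.39 ± 0.36 and -2.94 ± 0.36; their camera adjusted p was 7.35e-07, 0.000171 and 2.42e-06 (adjusted p = 0.0901, 0.207 and 0.11 with an estimated correlation). Glycolysis genes rose in A-iPSC, 14 of 26 higher and Slc2a3 lower (15 and 1 adjusted over the list alone), with Eno2 at 6.45 ± 0.61 (camera adjusted p = 0.000251; adjusted p = 0.207 with an estimated correlation). DNA repair genes fell in A-iPSC, 23 of 61 lower and 5 higher (29 and 6 adjusted over the list alone), with Apex1 at -3.26 ± 0.28 and Rpa2, a single-strand DNA binding subunit, at -2.80 ± 0.42 (camera adjusted p = 0.00101; adjusted p = 0.536 with an estimated correlation). Against ESC the DNA repair list also shifted down in Y-iPSC (6 lower, 0 higher; 6 and 0 adjusted over the list alone; camera adjusted p = 0.00304; adjusted p = 0.752 with an estimated correlation) and in A-iPSC-ZSCAN10 (5 and 0; 2 and 0 adjusted over the list alone; camera adjusted p = 0.0018; adjusted p = 0.672 with an estimated correlation). The glycolysis list shifted up in Y-iPSC too (7 higher, 0 lower; 8 and 0 adjusted over the list alone; camera adjusted p = 0.000716; adjusted p = 0.211 with an estimated correlation), but not past the threshold in A-iPSC-ZSCAN10 (3 and 0, also 3 and 0 adjusted over the list alone; camera adjusted p = 0.24). In the exosome list, 10 of 18 fell and 2 rose in A-iPSC (10 and 2 adjusted over the list alone; camera adjusted p = 0.0847), with Exosc5 at -1.43 ± 0.24 and Exosc2 at -1.85 ± 0.55. It had 2 higher and 1 lower in Y-iPSC and in A-iPSC-ZSCAN10 (the same numbers adjusted over the list alone; camera adjusted p = 0.328 and 0.924). Probes of Sox2 and Klf4 disagreed, while those of Pou5f1 lay close together. The brightest Sox2 probe was at 1.94 ± 0.39 in Y-iPSC, 1.68 ± 0.39 in A-iPSC and 0.69 ± 0.39 in A-iPSC-ZSCAN10, where it did not pass (adjusted p = 0.294). A second, not detected in these iPSC, was at least 6.73-fold, 6.02-fold and 6.42-fold lower. Klf4 was at 3.29 ± 0.56, 2.32 ± 0.56 and 2.25 ± 0.56 by its brightest probe and at -1.56, -2.14 and -3.85 by another.

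Distance to the ESC mean, the root mean square log2 difference over tested probes, was 1.099 ± 0.11 in Y-iPSC, 1.362 ± 0.0813 in A-iPSC and 1.032 ± 0.0791 in A-iPSC-ZSCAN10 (SD, n = 2), beside 0.382 between the 2 ESC arrays. Both A-iPSC arrays lay further than both Y-iPSC arrays and both A-iPSC-ZSCAN10 arrays, an order for which a two-sided exact permutation test of 2 against 2 arrays gives p = 0.333, the smallest it allows. Probes past the threshold numbered 2072 in Y-iPSC (1047 higher, 1025 lower), 5141 in A-iPSC (2533 and 2608) and 1809 in A-iPSC-ZSCAN10 (912 and 897). The last split was 1189 higher and 810 lower under median scaling and 891 and 1052 under cyclic loess. Y-iPSC minus ESC fell to 787 without ESC H, 1001 without ESC D and 1274 without Y-iPSC 4, and to 1087 with only its own groups. A-iPSC minus ESC was 2748 without A-iPSC 19, 3202 without ESC D and 2989 without ESC H. A-iPSC-ZSCAN10 minus ESC was 679 without A-iPSC-ZSCAN10 3, 1068 without A-iPSC-ZSCAN10 7, 877 without ESC D and 691 without ESC H, 4025 with only its own groups and 4764 with array weights.

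**Figure D3:**
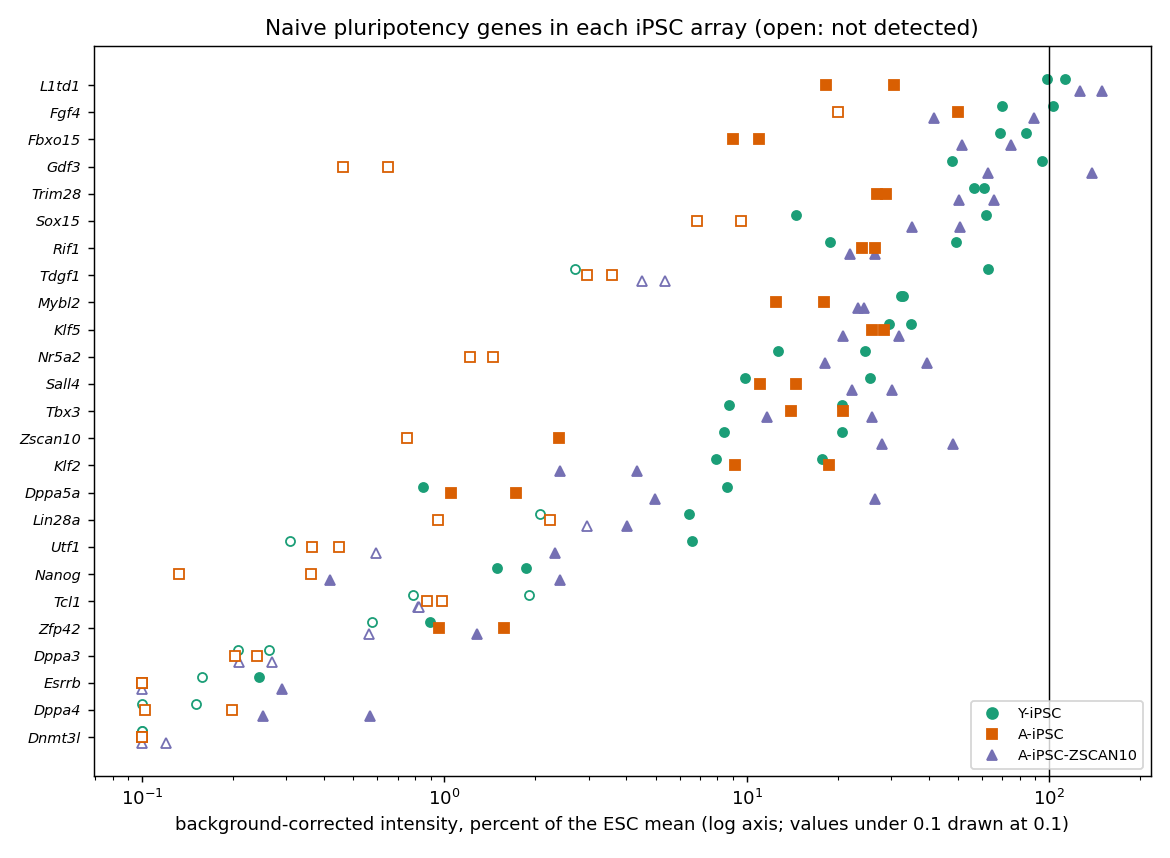
Signal above background of the 25 naive pluripotency genes on each iPSC array, as percent of the ESC mean (log axis; values under 0.1 drawn at 0.1; the line marks 100). The median share was 14.7% in Y-iPSC, 1.59% in A-iPSC and 18.8% in A-iPSC-ZSCAN10. The A-iPSC median is that of Lin28a, which neither A-iPSC array detected, so it is not a measured share.

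Aged and young fibroblasts differed at 61 probes, 28 higher and 33 lower in A-SC, in 48 genes (n = 3 arrays per group). Prelp rose by 4.82 ± 0.66 (adjusted p = 0.00831), Sod3, the extracellular superoxide dismutase, by 2.77 ± 0.35, the phosphatase gene Ptpn22 by 2.87 ± 0.28, Lmcd1 by 3.20 ± 0.50 and Hoxc13, a posterior homeobox gene, by 2.01 ± 0.32. Spink6, a protease inhibitor, was at least 5.2-fold higher and H2-DMb1 rose by 2.50 ± 0.37. The fetal growth factor Igf2 fell with -5.92 ± 1.07 and the fetal RNA binding protein Igf2bp1 with -3.62 ± 0.43. Sprr2k, Flt1, Lyz1 and Cxcl12 fell with -4.39 ± 0.40, -3.58 ± 0.66, -3.26 ± 0.47 and -2.17 ± 0.29. Among 11 immune cell markers, lysozyme Lyz2 fell with -3.33 ± 0.53 and complement C1qc was at least 4.3-fold lower (2 lower; 9 lower adjusted over the list alone; camera adjusted p = 6.84e-10; adjusted p = 0.203 with an estimated correlation). Glutathione genes shifted up with 0 of 37 past (7 higher adjusted over the list alone; camera adjusted p = 4.35e-05; adjusted p = 0.203 with an estimated correlation). Imprinted genes shifted down, with Igf2 the 1 of 25 past (5 lower adjusted over the list alone; camera adjusted p = 0.00376; adjusted p = 0.287 with an estimated correlation).

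These 61 probes rest on the pooled spread: a limma fit of the 6 fibroblast arrays alone gave 0 (1025 at an unadjusted p under 0.05). Of these arrays, 4 were exported in a second number format; with format as a block the count was 74, within that format 0 (1080 at an unadjusted p under 0.05), and without it 437 from 1 array per group. It was 92 without Y-SC 16, 22 without A-SC 1.4, 37 without background correction, 40 with normexp, 36 on the authors' table and 26 without a filter. Of these fits, those with any call had more probes higher than lower, except the fit without A-SC 1.4 with 11 of each, so the direction of the majority is not settled. Sex-linked genes differed within both groups: Xist was at an intensity of 447.6, 360 and 490.4 in Y-SC 16, A-SC 1.3 and A-SC 1.4, where Eif2s3y was not detected, while Y-SC 1, Y-SC 17 and A-SC 1 had Eif2s3y and no detected Xist. Without probes on the X and Y chromosomes the count was 59.

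Between fibroblasts and iPSC, 3450 probes differed in young cells (1718 higher, 1732 lower in Y-iPSC than in Y-SC) and 4861 in aged cells (2590 and 2271). There were n = 2 iPSC and 3 fibroblast arrays. The labels give 10% serum (FBS) and no LIF for fibroblasts, and 15% FBS with 1000 U/ml LIF for iPSC. Culture medium is therefore confounded with reprogramming. Pou5f1, which encodes Oct4, was at least 209-fold higher in Y-iPSC and rose by 7.13 ± 0.29 in A-iPSC. Not every A-SC array detected Pou5f1, so the size in A-iPSC depends in part on the offset. By its brightest probe, Sox2 was at least 70.6-fold and 58.4-fold higher. A second Sox2 probe was detected on 0 arrays of Y-SC, A-SC, Y-iPSC and A-iPSC and showed no rise. Whether the brightest Sox2 probe reads the retroviral Sox2, or the Pou5f1 probe the retroviral Oct4, stays open. L1td1 was at least 110.4-fold and 24.9-fold higher, and Sall4, a pluripotency zinc finger factor, at least 24.6-fold and 19.5-fold. Slc38a5 and Klk1, a kallikrein, were at least 379-fold and 95.3-fold higher in Y-iPSC and 268-fold and 154-fold in A-iPSC. Zscan10 was at least 3.8-fold higher in Y-iPSC than in Y-SC, and did not pass in A-iPSC against A-SC, where 1 of 2 and 0 of 3 arrays detected it. Gpx2 was at least 31.8-fold higher in A-iPSC than in A-SC. Slc2a3 rose by 5.51 ± 0.52 in the young pair.

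Matrix genes fell in each, 31 of 38 lower and 0 higher (34 and 35 lower adjusted over the list alone): the thrombospondin gene Thbs1 fell with -5.83 ± 0.75 and Dcn, decorin, with -5.90 ± 0.95 in the aged pair, Thy1 with -5.53 ± 0.49 and the lysyl oxidase Loxl1 with -5.27 ± 0.45 in the young pair. Camera adjusted p was 2.99e-17 and 1.25e-18 (adjusted p = 0.108 and 0.0653 with an estimated correlation). Smooth muscle markers had 7 of 8 lower in each pair (7 and 7 adjusted over the list alone), with Acta2 at -3.37 ± 0.22 and -3.21 ± 0.22 (camera adjusted p = 1.2e-05 and 0.000219; adjusted p = 0.108 and 0.156 with an estimated correlation). Senescence and secretory genes fell, 12 and 14 of 28 lower with 2 and 3 higher (14 and 18 lower adjusted over the list alone), with Igfbp3 among the higher and Csf1 at -5.02 ± 0.37 and -5.56 ± 0.37 (camera adjusted p = 0.00163 and 0.000166; adjusted p = 0.108 and 0.0653 with an estimated correlation). Glycolysis genes rose, 13 and 15 of 26, with 0 lower (14 and 15 adjusted over the list alone), Pdk1, a pyruvate dehydrogenase kinase, at 3.04 ± 0.31 and 3.32 ± 0.31 (camera adjusted p = 3.42e-05 and 6.74e-05; adjusted p = 0.114 and 0.156 with an estimated correlation). Naive pluripotency genes rose in the young pair, 11 of 25 higher and 2 lower (11 and 2 adjusted over the list alone; camera adjusted p = 3.42e-05; adjusted p = 0.204 with an estimated correlation), and had 3 higher and 1 lower in the aged pair (3 and 1 adjusted over the list alone; camera adjusted p = 0.429). Dnmt3l, in the same list, was at least 1.78-fold lower in the young pair and 4.3-fold lower in the aged pair, as no iPSC array detected it. Oxidative phosphorylation genes shifted up in the young pair with 2 of 61 higher and 0 lower (0 adjusted over the list alone; camera adjusted p = 0.0213; adjusted p = 0.803 with an estimated correlation), but their median was below 0 under median scaling.

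All iPSC arrays share 1 export format, and with format as a block the counts were 2557 and 3893; without the 4 arrays of the second format they were 1970 and 3748. Without Y-iPSC 4 the young count was 2152, with only its own groups 1670. The aged count was 2753 without A-iPSC 19 and 3124 without A-iPSC 16.

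The change at reprogramming itself differed with donor age at 562 probes in 399 genes, 353 higher and 209 lower in the aged pair. Gpx2 (5.66 ± 0.34), Htr2b (6.89 ± 0.51), Gsta3 (6.06 ± 1.18) and the potassium channel gene Kcnk13 (6.26 ± 0.92) were higher in this difference. Slc2a3 (-5.60 ± 0.74), Krt42 (-6.93 ± 0.70), Gdf3 (-5.95 ± 0.48), Fbxo15 (-3.08 ± 0.34) and Zscan10 (-2.03 ± 0.49, adjusted p = 0.0448) were lower in it. The call of Zscan10 was lost under most alternatives, among them no background correction, normexp, array weights and the fits without A-iPSC 16 or A-iPSC 19; without the 4 second-format arrays the calls of Slc2a3, Kcnk13 and Gsta3 were lost too. Several of these genes were not detected in some of the 4 groups, so their fitted sizes depend on the offset added to the signal. Of 25 naive pluripotency genes, 5 were lower in this difference and 0 higher (7 and 0 adjusted over the list alone; camera adjusted p = 6.63e-05; adjusted p = 0.882 with an estimated correlation). Cell cycle genes shifted down with 0 of 38 past (camera adjusted p = 0.000812; adjusted p = 0.882 with an estimated correlation), and without the 4 second-format arrays the list median was 0.96. Immune cell markers shifted up with 0 of 11 past (7 higher adjusted over the list alone; camera adjusted p = 0.00207; adjusted p = 0.882 with an estimated correlation). The exosome cofactor gene Ttc37 was at 2.16 ± 0.28 and Rad52 at 2.16 ± 0.31. With export format as a block the count was 685, and with only the 4 groups 268. Without the 4 second-format arrays it was 302, and the majority turned, with 132 higher and 170 lower. It was 218 without A-iPSC 19, 315 without A-SC 1.4, 364 without A-iPSC 16, 906 without A-SC 1 and 1079 without Y-iPSC 12.

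**Figure D4:**
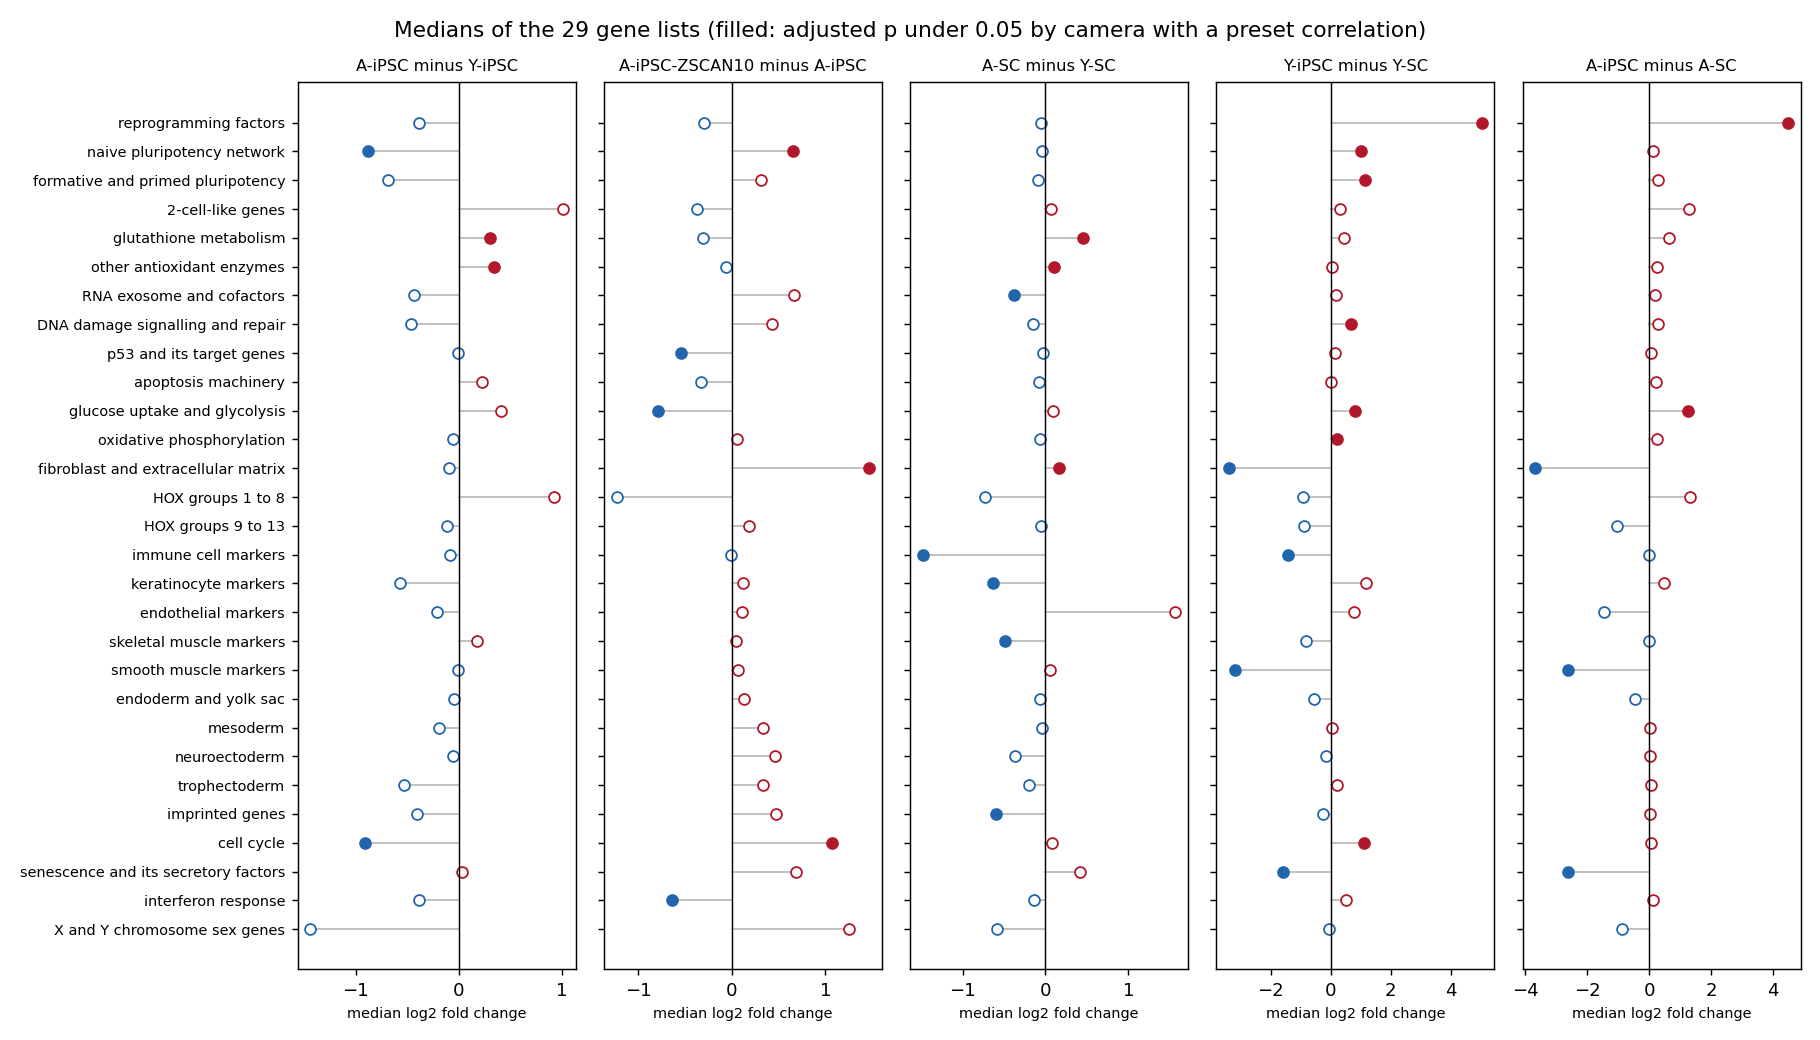
Median log2 fold change of the 29 gene lists in the 5 main comparisons; filled points had a camera adjusted p below 0.05. The naive pluripotency list lies below 0 in A-iPSC minus Y-iPSC and above 0 in A-iPSC-ZSCAN10 minus A-iPSC.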

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

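The tests of the naive pluripotency, fibroblast and Eif2s3y patterns were chosen only after the result was seen, and the splits of the fibroblast arrays before. The naive pluripotency genes lay far below ESC in each iPSC group, with median shares of ESC signal of 14.7% in Y-iPSC, 1.59% in A-iPSC and 18.8% in A-iPSC-ZSCAN10. In A-iPSC the middle gene, Lin28a, was detected on neither array, so 1.59% is not a measured share. Dilution of ESC-like cells by cells that lack these genes would leave every gene near 1 share, and the values argue against it as the whole cause: among the 15 members that fibroblasts lacked, the third highest share was 10.6, 7.1 and 22.2 times the fifth lowest in Y-iPSC, A-iPSC and A-iPSC-ZSCAN10 (68.6% over 6.46%, 9.03% over 1.27% and 51.6% over 2.32%). Scaling was argued against as well, since at least 15 members were called lower in each iPSC group under 5 other scalings, beside 17 to 24 reported. Probes that read the retroviral factors remain open as a source for Sox2 and Klf4. Their probes disagree more than those of at least 99.89% of genes with several probes (99.81% with dim values raised to the detection limit). Pou5f1, also introduced by retrovirus, lay at 43.41%. That value cannot decide, as probes that all read the introduced copy, or all miss it, would lie close together. A lower activity of the naive network in these iPSC may remain as a hypothesis, and donor age, line and culture history were not tested.

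Fibroblast genes were higher in A-iPSC-ZSCAN10 than in A-iPSC, 17 of 38 listed. Fibroblasts of these arrays mixed into cells at the A-iPSC level would lift all abundant fibroblast genes to the level of 1 share. In A-iPSC-ZSCAN10 3, at least 48% of 50 such genes lay over 1 log2 unit from the level of any share tried. So did at least 29.4% of the 17 listed genes that rose. These values argue against that mixture as the whole cause there. They cannot judge a mixture with cells at another level. Col4a1 and Col4a2, among the 50, were themselves lower in A-iPSC than in Y-iPSC. In A-iPSC-ZSCAN10 7 the lowest such percents were 22% of the 50 genes and 11.8% of the 17. These are too few to decide, so mixture and expression cannot be told apart in that array. Shares there ran from -2% (Thy1) to 81.2% (Atf5) in the 50 genes and from 5.52% to 96.1% in the 17. In A-iPSC-ZSCAN10 3 they ran from -2.91% to 143% and from 8% to 671% (Tgfbi). Scaling was argued against, since at least 11 members were higher under 5 other scalings. Mesenchymal expression in these lines, or cells of a type not on these arrays, could remain and was not tested.

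Y-linked Eif2s3y had intensities of 1127 and 734.3 in A-iPSC-ZSCAN10 but 156.8 and 113.1 in A-iPSC, where the first was detected and the second not; in Y-iPSC it was 1016 and 115.5. Xist was 446.3 in Y-iPSC 4, and 117.7 and 120.5 in A-iPSC, not detected; among the fibroblasts it was on in Y-SC 16, A-SC 1.3 and A-SC 1.4 alone. Of the calls between A-iPSC-ZSCAN10 and A-iPSC, 2.98% lay on X and Y, and 2254 calls were left without those probes. Most calls thus lay on other chromosomes. X held 198 of the expressed genes compared, beside 146 on chromosome 18 and 573 on chromosome 11, so its share of calls would be low in any case. An effect of sex on autosomal genes cannot be judged from this share. Lines with 2 active X chromosomes cannot be told apart from other causes. X-linked genes were higher in A-iPSC by a median of 0.254, beside autosome medians of -0.249 to 0.262, the highest being chromosome 12. Against the iPSC arrays of the other groups, the X median was 0.199 in A-iPSC 16, 0.21 in A-iPSC 19 and 0.107 in Y-iPSC 4. In Y-iPSC 12, A-iPSC-ZSCAN10 3 and A-iPSC-ZSCAN10 7, where Eif2s3y was higher, it was -0.137, -0.153 and -0.255. This order was not tested. Among other Y-linked genes, Kdm5d was 246.4 and 221.3 in A-iPSC-ZSCAN10 and 278.1 in Y-iPSC 12. It was not detected in A-iPSC, Y-iPSC 4 or ESC, while Uty was detected on every array. Eif2s3y was 262.9 in ESC D and 1028 in ESC H, so the Y-linked genes did not all go together. The labels do not give the sex of the donors, so a difference of donor sex between lines stays open and untested.

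The change at reprogramming differed between aged and young cells by a test of the difference itself at 562 probes. The named genes behind it were Htr2b at 6.89, Kcnk13 at 6.26, Gsta3 at 6.06, Gpx2 at 5.66, Krt42 at -6.93, Erdr1 at -6.47, 1110017D15Rik at -6.29, Slc2a3 at -5.60 and Zscan10 at -2.03 on the log2 scale. Apart from Gsta3 and Slc2a3, each of these genes was detected on 0 arrays of 1 or more of the 4 groups, so its size depends on the offset added to the signal and is not a measured fold.

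For the 61 probes between A-SC and Y-SC, the 10 splits of 3 against 3 arrays are too few for a share under 0.05; 1 split, the real one, gave as many, and the highest other gave 27.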

How the results depend on the processing

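The export format block, the fits without and within the second format, the fits without X and Y probes and the split of the A-iPSC arrays were tests chosen only after the result was seen. The planned block for slide was not run, as neither files nor labels give a slide. For all settings below, the cause of the difference was not tested. Under median scaling the median of all probes was 0.162 in A-iPSC-ZSCAN10 minus A-iPSC, 0.118 in A-iPSC-ZSCAN10 minus Y-iPSC and -0.121 in A-SC minus Y-SC, beside 0.0345, 0.0149 and -0.0304 in the reported fit. It turned the oxidative phosphorylation list in Y-iPSC minus Y-SC to -0.06562. The A-SC minus Y-SC count of 61 was 37 without background correction, 40 with normexp at offset 50, 36 on the authors' table and 26 without a filter on dim probes. With only the groups of the contrast, counts were 182 in A-iPSC minus Y-iPSC, 3910 in A-iPSC-ZSCAN10 minus A-iPSC, 0 in A-iPSC-ZSCAN10 minus Y-iPSC (limma; 1816 at an unadjusted p under 0.05), 1087 in Y-iPSC minus ESC, 4025 in A-iPSC-ZSCAN10 minus ESC, 0 in A-SC minus Y-SC (1025 unadjusted), 1670 in Y-iPSC minus Y-SC and 268 in the difference of reprogramming changes. Fibroblasts alone also gave 0 for A-SC minus Y-SC (limma, 1025 unadjusted). Array weights gave 4874 in A-iPSC-ZSCAN10 minus A-iPSC and 4764 in A-iPSC-ZSCAN10 minus ESC. Averaged probes turned Sox2 to -0.6509, -0.7827 and -1.205 in Y-iPSC, A-iPSC and A-iPSC-ZSCAN10 minus ESC. Gene list shifts numbered 73 and, with an estimated correlation, 4. With fry, which asks only whether a list's genes move on balance one way, 31 of the 73 did not pass and 28 other lists did.

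Without the 4 arrays of the second export format, 1 fibroblast array per group is left and is assumed to vary like the other groups. Counts were then 437 in A-SC minus Y-SC, 1970 in Y-iPSC minus Y-SC and 302 in the difference of reprogramming changes. List medians with another sign were, in A-SC minus Y-SC, -0.058 for fibroblast, -1.963 for cell cycle and 0.719 for interferon response genes, 1.098 for cell cycle genes in A-iPSC minus A-SC, and 0.3157 for DNA damage and 0.9561 for cell cycle genes in the difference of reprogramming changes. Within the second format, A-SC minus Y-SC had 0 probes (limma, 1080 unadjusted) and a DNA damage median of 0.2395. Leaving out 1 array leaves a lone array in groups of 2, assumed to vary like the other groups. The lowest and highest counts were 418 without A-iPSC 19 and 1830 without Y-iPSC 12 in A-iPSC minus Y-iPSC, 714 without A-iPSC 19 and 1439 without A-iPSC 16 in A-iPSC-ZSCAN10 minus A-iPSC, and 66 without A-iPSC-ZSCAN10 3 and 769 without Y-iPSC 12 in A-iPSC-ZSCAN10 minus Y-iPSC. Against ESC they were 787 without ESC H and 2201 without Y-iPSC 12 in Y-iPSC, 2748 without A-iPSC 19 and 3755 without A-iPSC 16 in A-iPSC, and 679 without A-iPSC-ZSCAN10 3 and 1068 without A-iPSC-ZSCAN10 7 in A-iPSC-ZSCAN10. They were 22 without A-SC 1.4 and 92 without Y-SC 16 in A-SC minus Y-SC, 2152 without Y-iPSC 4 and 3538 without Y-SC 1 in Y-iPSC minus Y-SC, and 2753 without A-iPSC 19 and 5301 without A-SC 1 in A-iPSC minus A-SC. The difference of reprogramming changes had 218 without A-iPSC 19 and 1079 without Y-iPSC 12, and opposite-sign calls 295 without A-iPSC 19 and 975 without Y-iPSC 12. With the A-iPSC arrays split between both contrasts, opposite-sign calls were 274 (A-iPSC 16 for A-iPSC minus Y-iPSC) and 375 (A-iPSC 19). The ratio of distances to ESC, A-iPSC over Y-iPSC, stayed within 1.157 and 1.334. For A-iPSC-ZSCAN10 over Y-iPSC it was 0.939 with all arrays, 0.8766 without Y-iPSC 12 and 1.01 without Y-iPSC 4, so its direction is not settled.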

Other observations

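No tests were made here beyond those of the gene lists, and the chromosomes named last were picked after their medians were seen. HOX genes of groups 1 to 8 were higher in iPSC than in ESC: 9 of 13 in A-iPSC (9 adjusted over the list alone; camera adjusted p = 0.00131; adjusted p = 0.527 with an estimated correlation), 3 in Y-iPSC (5 adjusted over the list alone; camera adjusted p = 0.00204; adjusted p = 0.674 with an estimated correlation) and 1 in A-iPSC-ZSCAN10 (1 adjusted over the list alone; camera adjusted p = 0.0185; adjusted p = 0.672 with an estimated correlation). Hoxd8 was at 5.98 ± 1.31 and Hoxb4 at 4.14 ± 0.55 in A-iPSC. Imprinted genes had 12 of 25 lower and 3 higher in A-iPSC than in ESC (12 and 3 adjusted over the list alone; camera adjusted p = 0.0827), with Mest at -4.49 ± 1.25 and Cdkn1c, an inhibitor of cell division, at -3.70 ± 0.94. Between the iPSC groups, Grb10, a growth inhibitor, was higher in A-iPSC than in Y-iPSC at 2.11 ± 0.32 and lower in A-iPSC-ZSCAN10 than in A-iPSC at -3.11 ± 0.32.

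Medians of autosomes, grouped by assembly GRCm38.p6, were compared between each iPSC array and the iPSC arrays of the other groups. Of 114 array and autosome pairs, 1 exceeded 3 SD (SD 0.121): chromosome 11 in Y-iPSC 4, at 0.39. Within 3 SD, chromosome 12 in A-iPSC 16 and A-iPSC 19 (0.28 and 0.32), chromosome 10 in A-iPSC-ZSCAN10 3 (0.29) and 4 other pairs also had at least 90% of their blocks of neighbouring genes above 0. The cause was not tested.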
